A study of Homo sapiens with 21 samples.

How the data were processed

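Open chromatin was measured by ATAC-seq, in which the Tn5 transposase cuts and tags accessible DNA, in 21 libraries of HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen. Per the labels, the cells were stably transfected and transgenes were induced for 48 h with 1 µg/ml doxycycline. The 7 groups of 3 libraries were an empty vector (MOCK), MLL-AF6, AF6-MLL, both of these together (Co1), exMLL-AF6, AF6-shMLL, and both of these together (Co2). MLL is the gene KMT2A and AF6 the gene AFDN. The prefixes ex and sh are kept as the labels give them.

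The authors deposited whole-number read counts per gene row, not normalized, per the file header. Per the submitters' processing notes, bcl2fastq, Bowtie2, HTSeq and the genome build GRCh38 were used; their versions and settings are not given in the sources used here. Whether reads were counted over exons or gene bodies, whether strand was used, and how duplicate and mitochondrial reads were treated are likewise not given. These steps matter for the values: the table holds mitochondrial rows with 27.6% to 66.3% of a library's counts, and a count per gene is not a count per accessible site. The Tn5 offset and peak calling could not be checked from a gene table.

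The table had 55140 rows, of which 51986 carried 1 Ensembl gene ID and 3154 carried several, which hold reads of overlapping or same-named genes. Such rows are uncertain as to the gene. All 21 columns of counts were used. Chromosome, position and gene type came from a RefSeq table of GRCh38.p14 matched by symbol (34690 rows) or by an older symbol (1166 rows), and 19284 rows were not matched. Across the 15826 tested nuclear genes with a length, the Spearman correlation of mean count with gene length was 0.059; genes are not independent replicates.

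Total counts per library ran from 687567 to 1766257. Without mitochondrial rows and rows named as mitochondrial pseudogenes, 277380 to 766583 counts remained, and the median tested gene had 11 to 31 counts per library. In simulated counts with the real library sizes for MLL-AF6 vs MOCK (17926 genes tested), the test recovered 22% of genes changed 1.5-fold, 56% of those changed 2-fold, 92% of those changed 3-fold and 94% of those changed 4-fold. In that simulation 12 of 144 calls, or 8.33%, were unchanged genes. The gene-list test was checked in the same way.

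Counts were tested with edgeR 4.0.16 (R 4.3.3), with TMM factors, filterByExpr (17960 rows kept, 35 of them mitochondrial) and the robust quasi-likelihood F test. All 21 libraries entered one model with a mean per group. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. A log2 fold change is given with its standard error (SE), and CPM values are counts scaled to a common library size with the TMM factors, as mean ± SD of 3 libraries. Each fusion group was compared with MOCK, the matching groups of the sets were compared, co-expression was compared with each single fusion, and a non-additive contrast asked whether co-expression differed from the sum of both single effects on the log2 scale. Gene lists fixed before the data were examined were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over 29 lists per comparison, and again with an estimated correlation. List members were also adjusted over the list alone. The list of KMT2A and AFDN was reported by gene only.

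Genes named in the text follow a rule written before the data were examined: KMT2A and AFDN in each group, up to 8 genes higher and 8 lower by fold change among called, abundant, non-overlapping genes, and up to 3 called members of each list. For co-expression against single fusions and non-additive contrasts, up to 3 in each direction were taken. Some genes that the rule names are not reported here. The alternatives were RLE size factors, cyclic loess offsets, no filter on low counts, DESeq2 1.42.0, the replicate number as a block, centring of each chromosome (the mitochondrial genome counted as 1), and leaving out each library. After the data were seen, 4 more were added: centring of 10 Mb windows with at least 25 genes, leaving out mitochondrial genes and pseudogenes, rows with 1 gene ID, and a fit without the Co1 libraries. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).

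Every pair of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 1.05 to 5.91), so no library was taken as a copy of another. The values for exMLL-AF6 replicates 2 and 3 (1.05) and MOCK replicates 2 and 3 (1.07) were close to noise alone, with mitochondrial rows included. Each library was counted as 1 replicate, which this check does not establish. The titles number the replicates after the letters BR, which the labels do not spell out, and no label says whether they came from separate cultures, so p-values measure only the spread between these samples. Each fusion is represented by what the labels give as a stably transfected cell population, without further lines, so an effect of a fusion and a difference between cell populations are not separated by this design.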

Results

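Chromatin accessibility was profiled by gene in 21 ATAC-seq libraries of doxycycline-treated HEK293T cells, with 3 libraries in each of 7 groups. The fusions join parts of the cDNAs of KMT2A (MLL), a histone H3 lysine 4 methyltransferase, and AFDN (AF6), a cell junction scaffold, as in the translocation t(6;11) of acute leukaemia. The labels describe 2 sets: MLL-AF6 with its reciprocal AF6-MLL, co-expressed in Co1, and exMLL-AF6 with AF6-shMLL, co-expressed in Co2. Total counts ran from 687567 to 1766257 per library. The 3 Co1 libraries separated from the other 18 on the first principal component, which held 16.35% of the variance. On the second (8.18%) Co2 replicate 1 lay at -41.6 and the other Co2 libraries at -14.3 and -6.68, and on the third (7.38%) MOCK replicate 3 (30.9) and MLL-AF6 replicate 3 (-29.8) lay at opposite ends. In an F test over all groups, edgeR called 2660 of 17960 genes, and 400 when the Co1 libraries were left out of the fit.

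Counts at the source genes of the transgenes were examined first, since reads from transgene cDNA can be assigned to them. KMT2A (ENSG00000118058, chromosome 11, 118436492 to 118526832, GRCh38) had 33.6 ± 5.09 CPM in MOCK and was higher in every fusion group. It reached 204 ± 20.2 CPM with MLL-AF6 and 151 ± 8.56 with exMLL-AF6. Levels were higher in groups with a reciprocal fusion, at 1229.8 ± 129 CPM with AF6-MLL, 1518 ± 8.37 with AF6-shMLL, 466 ± 43.4 in Co1 and 2213 ± 78.2 in Co2 (SD, n = 3 each). AFDN (ENSG00000130396, chromosome 6, 167826564 to 167972023) had 30.9 ± 11.7 CPM in MOCK, 231 ± 21.4 with MLL-AF6, 117 ± 10.1 with exMLL-AF6, 99.7 ± 16.2 in Co1, 71.9 ± 12.3 with AF6-shMLL and 259 ± 17.1 in Co2. With AF6-MLL its level of 50.8 ± 14.4 CPM did not pass the test (log2 fold change 0.64 ± 0.19 SE, adjusted p = 0.134, edgeR). In Co1 AFDN had a log2 fold change of 1.66 against MOCK, and of 1.05, still called, with 10 Mb windows centred (window median 0.56). The KMT2A and AFDN rows do not separate transgene from chromosomal reads.

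**Figure D1:**
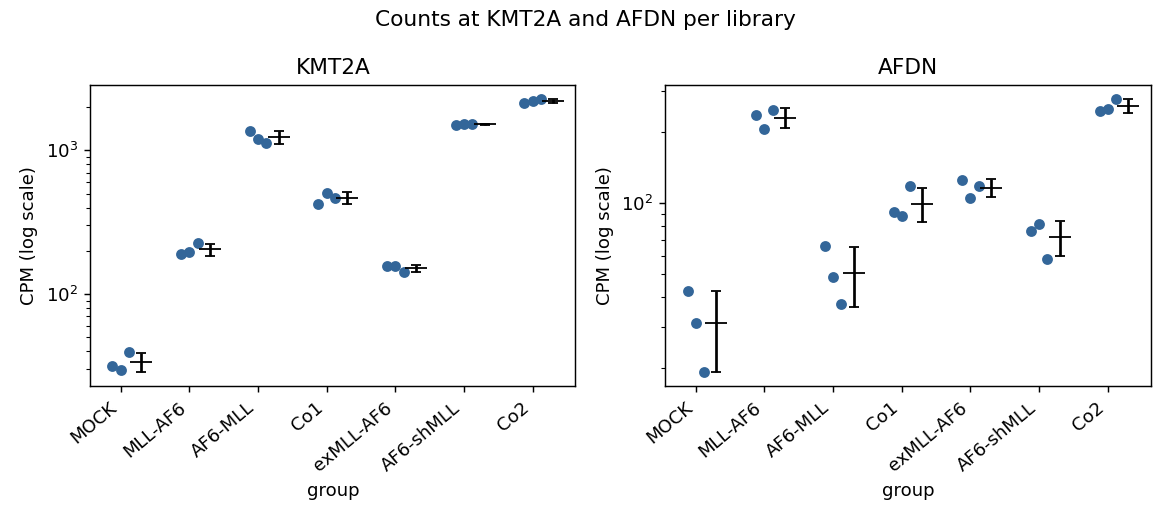
CPM (log axis) at KMT2A and AFDN in each library (points), with the group mean and SD (bar, n = 3). MOCK means were 33.6 CPM for KMT2A and 30.9 CPM for AFDN, and the Co2 means were 2213 and 259 CPM.

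The share of counts on the mitochondrial genome differed between MOCK and the fusion groups. It was 27.9% ± 0.338 in MOCK, 37.0% ± 5.47 with AF6-MLL, 46.8% ± 4.65 with MLL-AF6, 46.8% ± 2.11 with exMLL-AF6, 47.3% ± 5.78 in Co1, 50.6% ± 8.69 with AF6-shMLL and 58.7% ± 7.16 in Co2 (SD, n = 3). Each fusion group was above MOCK without overlap, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries can give. The list of mitochondrial genes passed the camera test against MOCK in all 6 groups, and with an estimated correlation in 4, with adjusted p = 0.301 for AF6-MLL and adjusted p = 0.0692 for Co1 with an estimated correlation. It did not pass with cyclic loess offsets (adjusted p from 0.0812 in Co2 to 0.79 in AF6-MLL), nor with each chromosome centred (0.842 to 0.994). Centring removes a shift of the mitochondrial genome by construction. Loess offsets follow abundance and can absorb a shift of rows that hold this large a share of the counts. Neither setting can therefore decide whether the share changed.

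**Figure D2:**
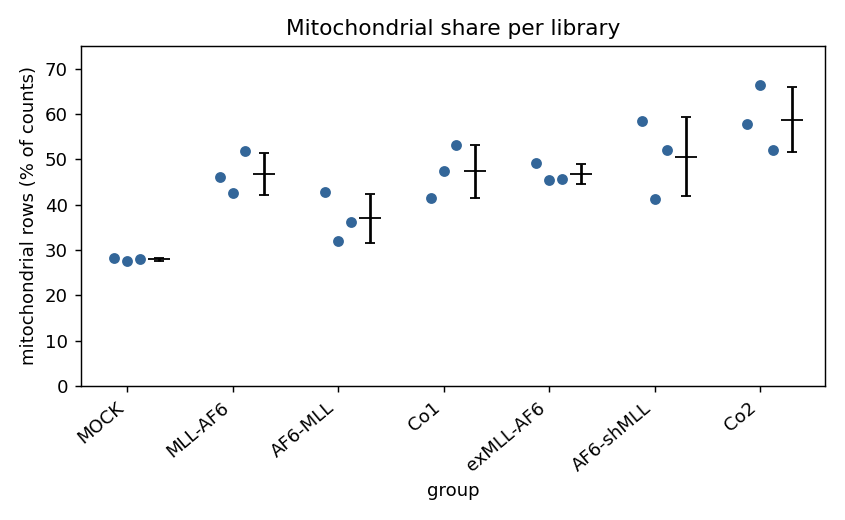
Mitochondrial rows as a percent of all counts in each library (points), with the group mean and SD (bar, n = 3). The MOCK libraries lie between 27.6% and 28.2%, below all other libraries.

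MLL-AF6 cells were compared with MOCK to ask which genes changed with this fusion alone. Besides KMT2A and AFDN, among called nuclear genes that were abundant and did not overlap between the groups' libraries, the highest fold change was at DHRS2, a short-chain dehydrogenase/reductase gene, at 41.0 ± 1.03 CPM against 13 ± 4.43 (3.19-fold, log2 fold change 1.67 ± 0.25 SE). HOXA4 of the HOXA cluster (1.44 ± 0.39), COL3A1, a fibrillar collagen (1.40 ± 0.40), and the immediate early gene EGR1 (1.05 ± 0.30) were higher. The ribosomal protein genes RPL13A (-1.16 ± 0.14) and RPL41 (-0.88 ± 0.17) were lower, as were the ATF4 targets CHAC1 (-0.74 ± 0.20) and TRIB3 (-0.79 ± 0.22), BACE1, the beta-secretase of amyloid precursor protein (-0.94 ± 0.26), and MXRA8 (-1.0 ± 0.25). The RPL13A row holds several gene IDs and is uncertain. Counts at RPL13A and RPL41 do not tell chromosomal reads from reads of a construct.

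By list, 1 of 10 HOXA genes rose and 0 fell, none of 9 HOXB, 9 HOXC or 6 HOXD genes passed the test, and 0 of 30 other MLL fusion targets did. Of 79 ribosomal protein genes 2 fell, and 2 of 27 ATF4 genes fell. The mitochondrial genome was the only list of 29 past the threshold: 31 of 35 genes rose, with a median log2 fold change of 1.32 (adjusted p = 7.51e-104, and adjusted p = 0.0203 with an estimated correlation). Its adjusted p was 0.716 with loess offsets, which can absorb such a shift. Mitochondrial reads made up 46.8% of the counts here and 27.9% in MOCK, and olfactory receptor genes, which are closed in most cells, 0.167% ± 0.00209 of the other counts here and 0.105% ± 0.0182 in MOCK. In all, edgeR called 278 genes, 202 higher and 76 lower (72.7% higher, against 53.9% with no filter on low counts and 90.8% with DESeq2). Leaving out MOCK replicate 2, MOCK replicate 3 or MLL-AF6 replicate 1 left 119, 120 and 135 calls, and DESeq2 called 98.

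AF6-MLL cells differed from MOCK at few genes. Apart from KMT2A, the called genes that were abundant and did not overlap between the groups' libraries included IDH3B, a subunit of the citric acid cycle's isocitrate dehydrogenase (37.2 ± 12.1 against 19.8 ± 1.19 CPM, log2 fold change 0.97 ± 0.23 SE), HMCN1 (0.89 ± 0.21), RASSF4 (0.80 ± 0.19) and the desmosomal cadherin DSC2 (0.75 ± 0.19), which were higher. MCM4, a replicative helicase subunit, was higher by 0.70 ± 0.16. CHAC1 (-1.15 ± 0.22), MRPL11 (-1.14 ± 0.28), MXRA8 (-1.14 ± 0.27), OXLD1 (-1.08 ± 0.24) and BEST1 (-1.03 ± 0.27) were lower. The HOXB list fell by camera, with a median log2 fold change of -0.40 over 9 genes (adjusted p = 0.00652), but adjusted p = 0.0896 with an estimated correlation and 0.208 with chromosomes centred; no HOXB gene was called over all genes and 1 was adjusted over the list alone. Of 35 mitochondrial genes, 0 were called and 18 rose when adjusted over the list alone (median 0.69, adjusted p = 2.00e-34, and adjusted p = 0.301 with an estimated correlation). edgeR called 51 genes, 17 higher and 34 lower. Without MOCK replicate 2 or 3, or AF6-MLL replicate 1, 2 or 3, the count was 21, 29, 33, 27 and 24, and DESeq2 called 28.

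Co1 cells, which carry MLL-AF6 and AF6-MLL together, differed most from MOCK. NHLH2, a neuronal basic helix-loop-helix factor, stood at 105 ± 0.982 CPM against 18.5 ± 3.11 (log2 fold change 2.47 ± 0.19 SE), and the transcription factor MYC at 183 ± 1.6 against 61.9 ± 3.1 (1.56 ± 0.12). CD164 (1.60 ± 0.18), FLRT2 (1.60 ± 0.27) and EGR1 (1.59 ± 0.29) were also higher. RIPPLY2 (-2.48 ± 0.34), FHOD3 (-2.16 ± 0.34), PLXDC2 (-2.14 ± 0.28), CELF4 (-2.05 ± 0.24), TRIB3 (-2.04 ± 0.28) and TPGS2 (-2.0 ± 0.17) were lower. FHOD3, CELF4 and TPGS2 lie in 1 window, at 30 to 40 Mb of chromosome 18, where the median of 37 genes was -1.44; with windows centred, an alternative added after seeing the data, TPGS2 was at -0.70 and still called, and CELF4 (-0.75, adjusted p = 0.0541) and FHOD3 (-0.87, adjusted p = 0.143) were not. Of 87 called genes that the naming rule picked in this comparison, 33 were no longer called with windows centred. NHLH2 (2.40), MYC (1.35), CD164 (0.95, in a window with a median of 0.69), RIPPLY2 (-2.95) and PLXDC2 (-1.35) still were. FLRT2 lies in no window with enough genes and was not centred.

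Within the HOX lists, 4 of 9 HOXB genes fell, among them HOXB5 (-1.25 ± 0.28), HOXB4 (-0.92 ± 0.24) and HOXB6 (-0.83 ± 0.22), and 7 fell when adjusted over the list alone. With windows centred HOXB5 was still called (-0.89), and HOXB4 (-0.56, adjusted p = 0.159) and HOXB6 (-0.47, adjusted p = 0.187) were not, beside a median of -0.36 in their window; 1 of 9 HOXB genes was then called, and the median of the list moved from -0.70 to -0.34. The list's adjusted p was 0.00112, and adjusted p = 0.0556 with an estimated correlation and 0.08 with chromosomes centred. In HOXC, 2 of 9 fell, with HOXC11 at -1.56 ± 0.25 and HOXC10 at -0.91 ± 0.24 (adjusted p = 0.032, and adjusted p = 0.0736 with an estimated correlation). HOXA9, a known MLL target, was higher (0.61 ± 0.19; adjusted p = 0.0607 with windows centred), HOXA6 lower (-1.22 ± 0.35), and HOXD9 lower (-2.61 ± 0.55); the HOXA6, HOXA9 and HOXC10 rows hold several gene IDs and are uncertain. Of 30 non-HOX MLL fusion targets 4 rose and 2 fell, and that list did not pass the test (adjusted p = 0.319).

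Of 27 mesenchymal and matrix genes 4 rose and 1 fell: SNAI2, a repressor active in epithelial-mesenchymal transition (1.59 ± 0.26), and the basement membrane collagen COL4A2 (1.5 ± 0.25) rose, while VIM, vimentin, fell (-0.73 ± 0.15). The windows of COL4A2 and VIM had medians of 1.13 and -0.93, and with windows centred COL4A2 was at 0.43 (adjusted p = 0.346) and VIM at 0.07 (adjusted p = 0.858), neither called, whereas SNAI2 was called at 1.45. That list's adjusted p was 0.032, and adjusted p = 0.0692 with an estimated correlation. Of 28 immediate early genes 5 rose, including KLF4 (0.96 ± 0.21), with an adjusted p of 0.049, and adjusted p = 0.183 with an estimated correlation and 0.127 with chromosomes centred. Of 348 ZNF genes 26 rose and 28 fell, with ZNF682 (2.73 ± 0.39) and ZNF331 (2.58 ± 0.30) up and ZNF397 down (-1.41 ± 0.19); ZNF397 was at -0.11 (adjusted p = 0.831) with windows centred. Of 25 SWI/SNF genes 4 rose and 4 fell, among them ARID1B (0.67 ± 0.11) and SS18 (-1.14 ± 0.19). Their windows had medians of 0.66 and -1.03, and with windows centred neither was called, at 0.07 (adjusted p = 0.816) and -0.17 (adjusted p = 0.693). All 35 mitochondrial genes rose (median 1.41, adjusted p = 1.85e-55, and adjusted p = 0.0692 with an estimated correlation). edgeR called 2492 genes, 1264 higher and 1228 lower; with no filter on low counts it called 767 higher and 1118 lower, and the balance also turned slightly with loess offsets, without mitochondrial genes and pseudogenes, and without any 1 MOCK library. DESeq2 called 1230, and with 10 Mb windows centred 1280 were called, 852 of them in a centred window; CDH2, IDI1, GATA3 and VIM then turned direction.

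**Figure D3:**
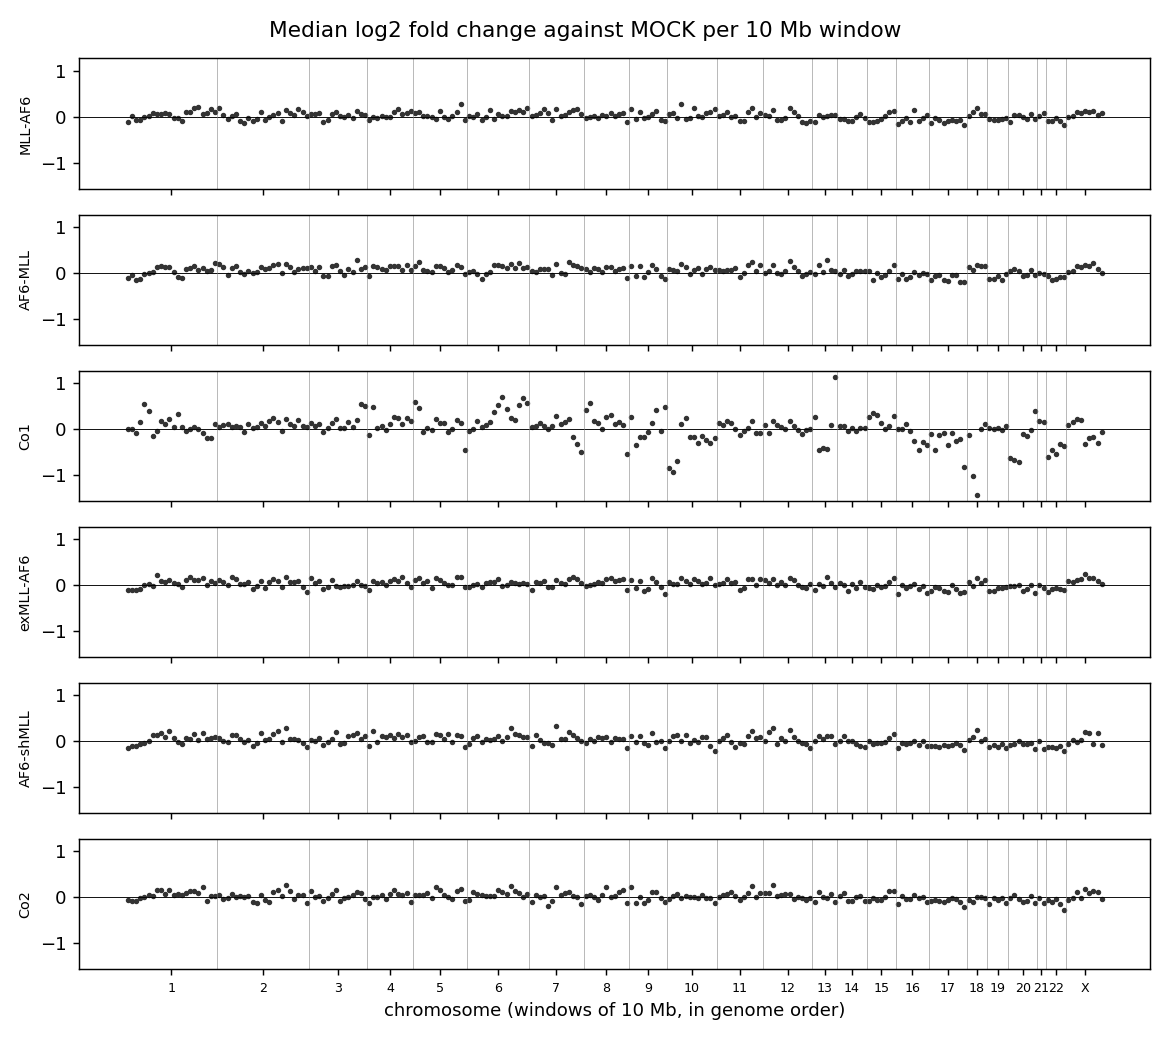
Median log2 fold change against MOCK of the tested genes in each 10 Mb window with at least 25 genes (points), in genome order, by group. In Co1, 52 of 235 windows lie beyond 0.3 in either direction, from -1.44 on chromosome 18 to 1.13 on chromosome 13, and at most 1 window does in any other group.

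exMLL-AF6 cells, compared with MOCK, had lower counts at 2 of 79 ribosomal protein genes and higher counts at 1, and that list did not pass the camera test. AC010619.2, whose gene ID is also in the RPL13A row, was at 141 ± 5.99 CPM against 416 ± 18.0 in MOCK. RPL13A, whose row holds several gene IDs, stood at 54.2 ± 20.2 CPM against 129 ± 17.3 (log2 fold change -1.25 ± 0.14 SE) and RPL41 at -0.85 ± 0.17, whereas RPL37 was higher (0.59 ± 0.14). The RPL13A and RPL41 counts do not tell chromosomal reads from reads of a construct. CHAC1 (-0.79 ± 0.20) and TRIB3 (-0.81 ± 0.22) were lower and DDIT4, another ATF4 target, was higher (0.72 ± 0.17). GAS8 (-1.05 ± 0.26), TMEM184A (-0.99 ± 0.21) and WDTC1 (-0.83 ± 0.22) were lower, and the AP-1 subunit JUN was higher (0.44 ± 0.11). No HOX gene was called. The mitochondrial list rose (25 of 35 called, median 1.3, adjusted p = 1.82e-117, camera), beside a mitochondrial share of 46.8%. Its adjusted p was 0.0119 with an estimated correlation and 0.709 with loess offsets, which can absorb such a shift. edgeR called 135 genes, 94 higher and 41 lower. The higher share was 69.6%, and 54.5% with loess offsets; leaving out MOCK replicate 2 or 3, or exMLL-AF6 replicate 1, 2 or 3, gave 81, 74, 80, 84 and 70 calls.

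AF6-shMLL cells had higher EGR1 than MOCK cells, at 34.3 ± 2.84 against 10.3 ± 3.55 CPM (log2 fold change 1.75 ± 0.28 SE). HSPA5, an endoplasmic reticulum chaperone (0.74 ± 0.16), PMAIP1, a p53-induced apoptosis gene (0.89 ± 0.23), the ETS factor ETV1 (0.72 ± 0.17) and ZNF608 (0.95 ± 0.21) were also higher. ICK (-1.12 ± 0.29), RNF115 (-1.03 ± 0.25), RREB1 (-0.90 ± 0.25), POLRMT, the mitochondrial RNA polymerase (-0.89 ± 0.24), and ZNF140 (-0.62 ± 0.15) were lower. The non-HOX MLL fusion targets rose as a list (median 0.20 over 30 genes, adjusted p = 0.0113, and adjusted p = 0.0456 with an estimated correlation), with 0 called over all genes and 1 adjusted over the list alone; the adjusted p was 0.0912 with chromosomes centred. The 348 ZNF genes fell as a list (median -0.12, adjusted p = 0.00553, and adjusted p = 0.0011 with an estimated correlation), with 1 gene higher and 1 lower, and adjusted p = 0.124 with chromosomes centred. Of 35 mitochondrial genes 34 rose (median 1.59, adjusted p = 3.05e-156, and adjusted p = 0.00156 with an estimated correlation). edgeR called 145 genes, 103 higher and 42 lower; without mitochondrial genes and pseudogenes 75 were called, 41 higher and 34 lower. Leaving out MOCK replicate 3 gave 92 calls, DESeq2 95, and the higher share of 71.0% was 57.1% with loess offsets.

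Co2 cells, which carry exMLL-AF6 and AF6-shMLL together, also had higher EGR1 (32.7 ± 3.24 against 10.3 ± 3.55 CPM, log2 fold change 1.71 ± 0.28 SE), ETV1 (0.74 ± 0.17) and HSPA5 (0.66 ± 0.16) than MOCK. RPL41 was higher (0.55 ± 0.15), in counts that do not tell chromosomal reads from reads of a construct. DIAPH2 (-1.05 ± 0.27), DHRS13 (-1.04 ± 0.24), TRIB3 (-0.88 ± 0.23), SLC1A4, a neutral amino acid transporter (-0.87 ± 0.23), and CCS, the copper chaperone of superoxide dismutase (-0.85 ± 0.22), were lower. Of 348 ZNF genes 3 fell, ZNF302 (-1.31 ± 0.31), ZNF862 (-0.78 ± 0.16) and ZNF627 (-0.69 ± 0.19), and the list fell (median -0.14, adjusted p = 0.0077, and adjusted p = 0.000336 with an estimated correlation; 0.13 with chromosomes centred). No HOX gene and no other MLL fusion target was called. All 35 mitochondrial genes rose (median 2.14, adjusted p = 4.11e-269, and adjusted p = 0.00017 with an estimated correlation), beside a mitochondrial share of 58.7%. edgeR called 143 genes, 100 higher and 43 lower, and 145 without Co2 replicate 1. Without mitochondrial genes and pseudogenes 64 were called, 33 higher and 31 lower. DESeq2 called 87, and the higher share of 69.9% was 59.3% with loess offsets.

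**Figure D4:**
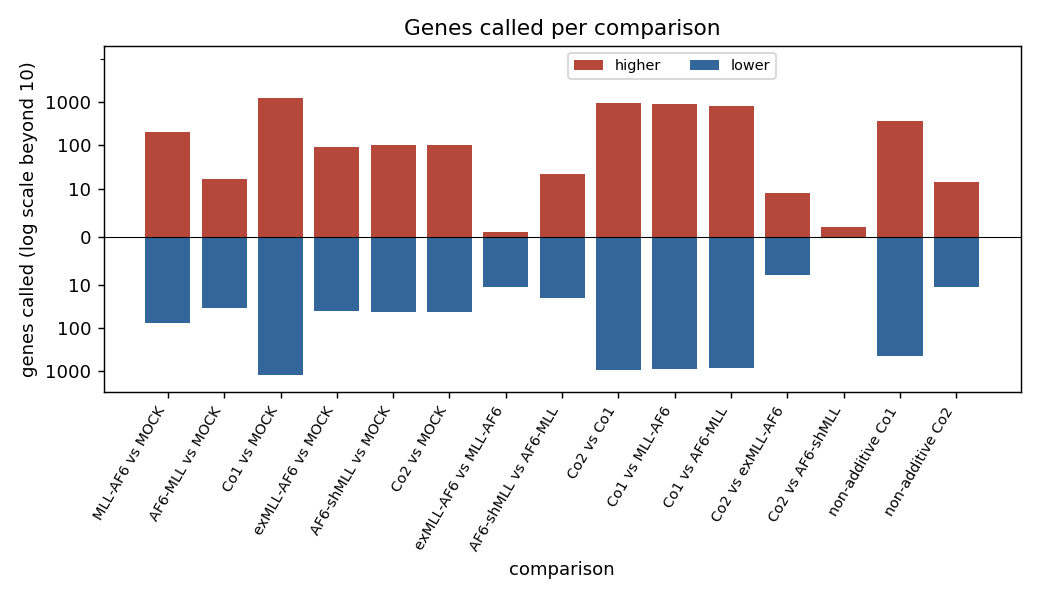
Genes called by edgeR at an adjusted p under 0.05 in each comparison, higher above and lower below 0 (axis logarithmic beyond 10). The counts range from 2 in Co2 vs AF6-shMLL to 2492 in Co1 vs MOCK.

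The sets were then compared fusion by fusion. Between exMLL-AF6 and MLL-AF6, AFDN was lower with exMLL-AF6 (log2 fold change -0.98 ± 0.12 SE) and KMT2A did not pass the test (-0.43 ± 0.20, adjusted p = 0.506, edgeR). ELF3, an epithelial ETS factor whose row holds several gene IDs, was lower (22.4 ± 4.53 against 50.3 ± 4.55 CPM, -1.20 ± 0.21), as were CFAP46 (-1.0 ± 0.23), SYNGR2 (-0.80 ± 0.19) and RGMA, a repulsive guidance molecule (-0.70 ± 0.14), and ACTR6 was higher (0.98 ± 0.20). As lists, ribosomal proteins (median 0.13, adjusted p = 0.00151), cell cycle genes (0.17, adjusted p = 0.0238) and nuclear oxidative phosphorylation genes (0.12, adjusted p = 0.0313) rose with 0 genes called and 4 ribosomal protein genes higher when adjusted over the list alone. With an estimated correlation the adjusted p values were 0.0941, 0.0941 and 0.155, and with loess offsets 0.0672, 0.097 and 0.097. edgeR called 12 genes, 1 higher and 11 lower. The count was 20 without MOCK replicate 1, 6 without exMLL-AF6 replicate 2 and 23 with chromosomes centred.

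Between AF6-shMLL and AF6-MLL, 1 HOX gene was called, and 3 of the 4 HOX lists passed the camera test, 2 of them also with an estimated correlation. HOXB rose as a list (median 0.43 over 9 genes, adjusted p = 1.94e-05, and adjusted p = 0.00538 with an estimated correlation), with HOXB3, a row of several gene IDs, called (61.2 ± 6.12 against 33.9 ± 11.4 CPM, log2 fold change 0.84 ± 0.20 SE) and 2 higher over the list alone. HOXC rose (median 0.43, adjusted p = 0.00149, and adjusted p = 0.0145 with an estimated correlation), with 0 called and 4 over the list alone. HOXA rose with 0 called (median 0.39, adjusted p = 0.0123, but adjusted p = 0.114 with an estimated correlation), and HOXD did not pass (adjusted p = 0.488). Against MOCK, HOXB fell with AF6-MLL at the preset correlation but not with an estimated one. No HOX list passed the camera test for AF6-shMLL against MOCK. These rises therefore do not show higher HOX counts with AF6-shMLL than in MOCK. The RAS-MAPK list also rose, with 0 of 40 called (median 0.13, adjusted p = 0.0261, and adjusted p = 0.0325 with an estimated correlation).

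Single genes of that comparison included EGR1 (1.20 ± 0.28) and HSPA5 (0.98 ± 0.18), which were higher, and ICK (-1.41 ± 0.29), CHCHD2 (-1.03 ± 0.25), CENPC, a centromere protein (-0.76 ± 0.18), and ZNF140 (-0.70 ± 0.15), which were lower. Immediate early genes (adjusted p = 0.0104) and replication histones (adjusted p = 0.0431) rose as lists, with adjusted p = 0.0602 and 0.111 with an estimated correlation, and ZNF genes fell (adjusted p = 0.0453, and adjusted p = 0.0119 with an estimated correlation, but 0.0583 with chromosomes centred). Mitochondrial genes rose (4 of 35 called, median 0.89, adjusted p = 6.81e-60, and adjusted p = 0.0325 with an estimated correlation). KMT2A (0.30 ± 0.18, adjusted p = 0.591) and AFDN (0.56 ± 0.17, adjusted p = 0.17) did not pass the edgeR test. edgeR called 42 genes, 22 higher and 20 lower, and neither direction held more calls in every setting: there were 16 higher and 26 lower without mitochondrial genes and pseudogenes and 21 higher and 29 lower with chromosomes centred, but 46 higher and 11 lower without AF6-shMLL replicate 2. Leaving out AF6-MLL replicate 2 or 3, or AF6-shMLL replicate 1 or 3, gave 16, 5, 18 and 12 calls, and DESeq2 gave 18.

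Between Co2 and Co1, KMT2A (log2 fold change 2.25 ± 0.19 SE) and AFDN (1.39 ± 0.12) were higher in Co2. RIPPLY2 (2.85 ± 0.33), PLXDC2 (2.26 ± 0.29) and ASXL3 (2.14 ± 0.29) were higher in Co2, and NHLH2 (-1.83 ± 0.18), ATP11A (-1.55 ± 0.24), NRARP (-1.52 ± 0.23) and MYC (-1.24 ± 0.13) were lower. With windows centred ASXL3 (0.80, adjusted p = 0.116) and ATP11A (-0.45, adjusted p = 0.322) were not called, in windows at -1.44 and 1.13 in Co1 vs MOCK, and PLXDC2 (1.44) and NRARP (-0.97) were called at smaller values. HOXB rose, with 4 of 9 genes called (median 0.70, adjusted p = 0.000102, and adjusted p = 0.00789 with an estimated correlation), among them HOXB5 (1.14 ± 0.29) and HOXB6 (1.09 ± 0.22). Their window lay at -0.36 in Co1 vs MOCK, and with windows centred 1 of 9 HOXB genes was called (median 0.39), HOXB6 at 0.78, while HOXB3 (0.58, adjusted p = 0.0659) and HOXB5 (0.83, adjusted p = 0.0782) were not. HOXC rose with 2 of 9 called (median 0.51, adjusted p = 0.0281, and adjusted p = 0.0765 with an estimated correlation), HOXC11 by 1.31 ± 0.27. Mitochondrial genes rose (9 of 35, median 0.73, adjusted p = 5.48e-19, and adjusted p = 0.286 with an estimated correlation). edgeR called 1926 genes, 966 higher and 960 lower (437 and 472 with windows centred, so neither direction held more calls throughout). Without Co2 replicate 3 it called 1109, with 10 Mb windows centred 909, and DESeq2 called 793.

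Co-expression was compared with each single fusion. Against MLL-AF6, Co1 cells had higher NHLH2 (log2 fold change 1.73 ± 0.17 SE), KCNG3 (1.59 ± 0.26) and MYC (1.48 ± 0.13) and lower PLXDC2 (-2.48 ± 0.27; -1.59 with windows centred) and ASXL3 (-2.43 ± 0.27; -0.92 and adjusted p = 0.0505 with windows centred), with 1827 genes called; KMT2A was higher (1.19 ± 0.20) and AFDN lower (-1.20 ± 0.12). Against AF6-MLL, KMT2A was lower (-1.40 ± 0.19) and AFDN higher (1.02 ± 0.16; 0.53 with windows centred). NHLH2 (2.45 ± 0.20), NRARP (1.73 ± 0.24; 1.12 with windows centred) and MYC (1.56 ± 0.13) were higher and PLXDC2 (-2.56 ± 0.28; -1.68 with windows centred) and RIPPLY2 (-2.49 ± 0.35) lower, with 1636 genes called and 1047 without AF6-MLL replicate 3. DESeq2 called 814 and 720, and with windows centred 811 and 694 were called. Co2 cells differed from exMLL-AF6 cells at 17 genes, with higher KMT2A (3.87 ± 0.21), RPL41 (1.40 ± 0.17) and RPL13A (1.25 ± 0.14) and lower GPATCH2 (-1.20 ± 0.27) and EIF4G2 (-0.72 ± 0.15). That count was 7, 8 and 9 without exMLL-AF6 replicate 1, 2 or 3, 9 without Co2 replicate 2, and 43 with no filter on low counts. The RPL41 and RPL13A counts here do not tell chromosomal reads from reads of a construct. Co2 differed from AF6-shMLL at 2 genes, AFDN (1.85 ± 0.13) and RF01518 (0.66 ± 0.13), a row of several gene IDs; 7 were called with loess offsets, and 1 was called without AF6-shMLL replicate 2 or 3 or Co2 replicate 3. By list, ribosomal proteins rose in Co1 against MLL-AF6 (10 of 79 called, adjusted p = 0.0127), and immediate early genes (6 of 28, adjusted p = 0.00894) and replication histones (2 of 30, adjusted p = 0.0376) rose against AF6-MLL; with an estimated correlation the adjusted p values were 0.202, 0.217 and 0.22. Immediate early genes rose in Co2 against exMLL-AF6 with 0 called (adjusted p = 0.0132, but adjusted p = 0.091 with an estimated correlation). Mitochondrial genes rose as a list in Co1 against AF6-MLL (5 of 35 called, adjusted p = 9.43e-19), and with 0 called in Co2 against exMLL-AF6 (adjusted p = 1.52e-58) and against AF6-shMLL (adjusted p = 8.86e-34); with an estimated correlation the adjusted p values were 0.328, 0.0873 and 0.463.

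The non-additive contrasts asked whether co-expression departed from the sum of the single effects on the log2 scale, which is the product of the single fold changes. Where both fusions raise a row, counts that simply add up lie below that product. This applies to KMT2A and the mitochondrial list, so a value below the sum does not by itself show less than additive counts there. In Co2 KMT2A had 2213 CPM, more than exMLL-AF6 (151) and AF6-shMLL (1518) together. In Co1 KMT2A had 466 CPM, against 204 with MLL-AF6 and 1229.8 with AF6-MLL. The Co1 level was below that with AF6-MLL alone, and so less than additive on the count scale too. In Co1, CHAC1 (log2 difference 2.09 ± 0.30 SE), MXRA8 (2.23 ± 0.38) and ELL3 (1.99 ± 0.33) lay above the sum, and PLXDC2 (-2.91 ± 0.34; -1.93 with windows centred) and KMT2A (-4.01 ± 0.30) below it. edgeR called 800 genes, 363 above and 437 below; DESeq2 called 297, and 308 were called with windows centred. With no filter on low counts 495 were called, 274 above and 221 below, so which direction held more genes depended on the filter. In Co2, RPL13A (1.61 ± 0.19), RIMBP3B (1.39 ± 0.31) and RF01518 (1.34 ± 0.17) lay above and KMT2A (-1.64 ± 0.30), EIF4G2 (-1.02 ± 0.21) and the protocadherin PCDH9 (-0.87 ± 0.17) below, with 25 genes called, 14 above and 11 below. The ELL3, RPL13A, RIMBP3B, RF01518 and EIF4G2 rows hold several gene IDs and are uncertain. For RPL13A, counts also do not tell chromosomal reads from reads of a construct. Mitochondrial genes lay below the sum as a list in both sets (median -0.64 and -0.74, adjusted p = 3.3e-09 and 1.95e-25), with 0 called and adjusted p = 0.514 and 0.336 with an estimated correlation.

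Effects of matching fusions against the shared MOCK libraries were set side by side. Across 17960 genes, which are not independent replicates, the log2 fold changes of MLL-AF6 and exMLL-AF6 correlated at 0.568, against a mean of 0.478 in 20 simulations of unchanged groups. In these, counts of all 21 libraries, MOCK included, were drawn anew from the MOCK mean and the fitted dispersions. The covariance of MLL-AF6 and exMLL-AF6 was 0.0757 against 0.0415 simulated. These 2 groups shared 49 higher and 19 lower calls, with no shared call of opposite direction, where independent lists would share 1.06 and 0.173. The simulations shared 0, which was to be foreseen for groups without change and is no yardstick for this overlap. Of the 49, 35 were mitochondrial genes or pseudogenes; without these, 14 higher calls were shared (0.522 for independent lists), with r = 0.554 and a covariance of 0.0707. For AF6-MLL and AF6-shMLL the correlation was 0.469 (simulated 0.429), the covariance 0.0626 (simulated 0.0414), and 5 higher and 10 lower calls, none of the higher ones mitochondrial, were shared (0.0975 and 0.0795 for independent lists). For Co1 and Co2 the correlation was 0.353 (simulated 0.44), the covariance 0.0731 (simulated 0.0415), and 76 higher and 24 lower calls were shared (7.04 and 2.94 for independent lists), with 3 of opposite direction. Of the 76, 53 were mitochondrial genes or pseudogenes, and without these 23 were shared (3.11 for independent lists), with r = 0.328 and a covariance of 0.0638. The 3 MOCK libraries do not allow a split with at least 2 in each part, so part of the overlap of calls beyond independent lists may come from the shared controls. For Co1 and Co2 the correlation lay below the simulated one and the covariance above it. The simulated groups were unchanged, whereas Co1 had 2492 calls, and a wider spread of fold changes in 1 group lowers a correlation. That lower correlation therefore does not show that Co1 and Co2 share less than unchanged groups.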

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

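Of the tests in this part, the neighbours of KMT2A and AFDN were set before their values were seen; those of the order of windows, window centring, mitochondrial share, the mitochondrial pattern and other splits of the libraries were chosen only after their results were seen. In both sets, genes departed from the sum of the single-fusion effects on the log2 scale, by a test of that difference itself: 800 genes in Co1 and 25 in Co2. For Co1, 1 of 100 splits of the 12 libraries, the real one, gave as many genes, and the highest other gave 672. For Co2, 3 of 100 splits gave as many, a share under 0.05, but the highest other split gave 49 genes, more than the real one, so the 25 genes do not stand above every other split. Such splits also mix libraries of groups that differ, so for both sets they exclude chance only as to whether the 4 groups are interchangeable, not as to whether the effects add up. With windows centred 308 genes were called in Co1 and 26 in Co2, and with DESeq2 297 and 20. Shifts of chromosome windows in Co1, described below, enter its contrast directly. Its 800 genes therefore need not reflect the fusions acting together. Over all 21 libraries, 1 of 100 splits, the real one, reached 2660 genes, and the highest other gave 1166.

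Co1 stood apart from the other groups. Against the share of mitochondrial reads as the cause, 3 groups with a share within 1 SD of that of Co1 had at most 278 calls against MOCK, where Co1 had 2492. A difference in copy number of chromosome segments may account for part of the pattern. Whole runs of 10 Mb windows shifted in Co1 against MOCK. On chromosome 10 the windows from 0 to 30 Mb had medians of -0.84, -0.93 and -0.70, and that at 40 to 50 Mb 0.09. On chromosome 20 those from 0 to 30 Mb had -0.63, -0.68 and -0.72, and that at 30 to 40 Mb -0.10. Chromosome 22 windows with enough genes lay between -0.62 and -0.33. Such runs go with copy number, which was not measured. Medians of neighbouring 10 Mb windows correlated at 0.61 in Co1, above the highest of 1000 shuffled orders (0.252). The correlation as such is not specific to Co1, since the other groups also exceeded theirs, at 0.294 to 0.448. It does not measure the size of the shifts, which did set Co1 apart. In Co1, 52 of 235 windows had a median beyond 0.3 in either direction, and at most 1 did in any other group. Of the Co1 calls in windows, 48.7% lay in these shifted windows, which held 21.7% of the genes. The windows were picked by the same fold changes that give the calls, so this share cannot tell for or against copy number. As to copy number as the whole cause, 852 of the 14631 genes in windows were called after centring. The highest other comparison with MOCK had 138. In Co1 the count was 1280 with the genes outside windows, which were not centred, and 1162 of the 1280 were also called without centring. Segments shorter than 10 Mb, or that end within a window, are not fully removed. Shifts of whole windows thus do not account for all Co1 calls, but copy number as the whole cause is not excluded. An effect of both fusions together and a difference between cell populations that arose before induction stay open, since the labels name no further Co1 line.

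Counts at KMT2A were higher in the 6 groups with transgenes than in MOCK, and those at AFDN in 5, while AFDN with AF6-MLL did not pass the test (0.64, adjusted p = 0.134). Against a gain or opening of the region around KMT2A, its 41 tested neighbours within 1 Mb had medians of at most 0.0372 (log2) in the 6 groups, where KMT2A rose by 2.18 to 6.05. For AFDN over all groups this stays open: the highest median of its 11 neighbours was 0.653, with MLL-AF6, where AFDN rose by 2.86 and 0 neighbours were called, and it was 0.652 in Co1, where 7 were called. In Co2, exMLL-AF6 and AF6-shMLL, AFDN rose by 3.05, 1.88 and 1.20. Its neighbours there had medians of 0.159, 0.152 and 0.039 (SD over neighbours 0.31, 0.32 and 0.28), with 0 called. This argues against a gain of the region in these groups, a reading by group that was not set beforehand. Reads from the transgene cDNA remain a candidate explanation, untested without the positions of reads within the genes.

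The mitochondrial share of counts was higher in the 6 fusion groups than in MOCK, but with AF6-MLL edgeR called 0 of 35 mitochondrial genes, and the list was not called with an estimated correlation there (adjusted p = 0.301) or in Co1 (adjusted p = 0.0692). Counts on pseudogenes named after mitochondrial genes followed the mitochondrial share, with r = 0.999 and rho = 0.997 over 21 libraries after group means were taken off (two-sided permutation p = 1e-05 for each, the smallest that 100000 permutations can give; r = 0.998 without the 2 libraries farthest from the median). This is consistent with mitochondrial reads counted at these copies, so their calls are not separate results. A single change of the whole mitochondrial share stays open in the 6 groups: after the 35 genes were centred together 3 were called with MLL-AF6 and AF6-MLL, 6 with exMLL-AF6 and AF6-shMLL and 8 in Co1 and Co2, and the bounds for reading these counts (at most 5% or over 20% of the genes in each group) were set after they were seen. The 35 log2 fold changes against MOCK had an SD from 0.0815 (MLL-AF6) to 0.128 (Co2), with medians from 0.692 (AF6-MLL) to 2.14 (Co2). The 35 genes thus moved largely together, and the calls after centring are small departures from a common shift. Nuclei preparation and mitochondrial DNA content were not told apart by any test here.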

How the results depend on the processing

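At these depths with 3 libraries per group, simulations recovered 22% of 1.5-fold and 56% of 2-fold changes; depth and number of libraries were not varied apart. The causes of the changes below were not tested unless stated. RLE size factors and the replicate block kept all 16 counts of called genes within 1.5 times. DESeq2 called fewer: 98 for MLL-AF6, 28 for AF6-MLL, 1230 for Co1, 95 for AF6-shMLL and 87 for Co2 against MOCK, 5 for exMLL-AF6 vs MLL-AF6, 18 for AF6-shMLL vs AF6-MLL, 793 for Co2 vs Co1, 814 and 720 for Co1 vs MLL-AF6 and vs AF6-MLL, 6 and 1 for Co2 vs exMLL-AF6 and vs AF6-shMLL, 297 for non-additive Co1 and 1068 for any group. No filter on low counts gave 86 (exMLL-AF6 vs MOCK), 43 (Co2 vs exMLL-AF6) and 495 (non-additive Co1). Loess gave 21 (exMLL-AF6 vs MLL-AF6) and 7 (Co2 vs AF6-shMLL). Chromosome centring gave 73 (exMLL-AF6 vs MOCK), 23 (exMLL-AF6 vs MLL-AF6) and 5 (Co2 vs AF6-shMLL). The other 4 settings were added after seeing the data. Window centring gave 31 (AF6-MLL vs MOCK), 1280 (Co1 vs MOCK), 909 (Co2 vs Co1), 811 and 694 (Co1 vs MLL-AF6 and vs AF6-MLL), 308 (non-additive Co1) and 1419 (any group). Leaving out mitochondrial genes and pseudogenes gave 75 (AF6-shMLL vs MOCK), 64 (Co2 vs MOCK) and 6 (Co2 vs AF6-shMLL). Rows with 1 gene ID gave 88 (exMLL-AF6 vs MOCK), and leaving out Co1 gave 400 (any group), as fewer groups differ. The share of higher calls moved by over 10 points with chromosome centring too: to 56.2% from 69.6% (exMLL-AF6), 58.3% from 71.0% (AF6-shMLL) and 55.9% from 69.9% (Co2) against MOCK, and to 42% from 52.4% for AF6-shMLL vs AF6-MLL; loess gave 63.2% from 52.9% for Co2 vs exMLL-AF6. Other settings moved it too: no filter to 53.9% from 72.7% (MLL-AF6 vs MOCK), 40.7% from 50.7% (Co1 vs MOCK), 66.7% (AF6-shMLL vs AF6-MLL) and 74.4% (Co2 vs exMLL-AF6), DESeq2 to 90.8%, 85.0%, 81.1% and 80.5% (MLL-AF6, exMLL-AF6, AF6-shMLL and Co2 vs MOCK), and leaving out mitochondrial genes and pseudogenes to 58.7%, 54.7% and 51.6% (exMLL-AF6, AF6-shMLL and Co2 vs MOCK) and 38.1% (AF6-shMLL vs AF6-MLL).

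Leaving out 1 library at a time gave 119 to 305 calls for MLL-AF6, 21 to 55 for AF6-MLL, 1815 to 2581 for Co1, 70 to 142 for exMLL-AF6, 92 to 159 for AF6-shMLL and 97 to 152 for Co2 against MOCK. It gave 6 to 20 for exMLL-AF6 vs MLL-AF6, 5 to 57 for AF6-shMLL vs AF6-MLL, 1109 to 1999 for Co2 vs Co1, 1251 to 1899 for Co1 vs MLL-AF6, 1047 to 1699 for Co1 vs AF6-MLL, 7 to 20 for Co2 vs exMLL-AF6, 1 to 2 for Co2 vs AF6-shMLL, 566 to 820 for non-additive Co1, 18 to 28 for non-additive Co2 and 1954 to 2792 for any group. Libraries with the same replicate number correlated between -0.114 and 0.0938 in their deviations (median 0.00182), and 8 of 21 were best matched by their own number, so the numbers do not pair the samples. With the replicate block the counts were 261, 51, 2474, 130, 129 and 130 against MOCK, in the order of groups above.

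Gene lists past the threshold numbered 37 over all comparisons; of these, 37 also passed with the block, 18 with loess offsets, 14 with chromosome centring and 13 with an estimated correlation, under which 15 passed in all, 2 of them not among the 37. Among genes at or above the median abundance, the correlations of matching fusions were 0.624, 0.526 and 0.411, against 0.475, 0.433 and 0.44 in simulations of unchanged groups, so that of Co1 and Co2 lay below; the covariances were 0.0509, 0.0465 and 0.0622 (simulated 0.0209, 0.0208 and 0.0209). Directions turned at these values. With loess, MT-ND3 was at -0.0552, -0.00413 and -0.0144 with MLL-AF6, AF6-shMLL and Co2 against MOCK. Chromosome centring, which removes a shift of the mitochondrial genome by construction, put MT-TK at -0.00201, -0.00256, -0.0804 and -0.0149 (MLL-AF6, AF6-shMLL and Co2 against MOCK, AF6-shMLL vs AF6-MLL) and turned the mitochondrial list at adjusted p 0.933 (MLL-AF6), 0.994 (AF6-MLL), 0.842 (AF6-shMLL) and 0.994 (Co2) against MOCK, 0.993 (AF6-shMLL vs AF6-MLL) and 0.969 (Co2 vs Co1). Window centring turned CDH2 (0.0142), IDI1 (0.119), GATA3 (0.0481) and VIM (0.0713) in Co1 vs MOCK and IDI1 (-0.231), COL4A2 (0.0356) and VIM (-0.0826) in Co2 vs Co1. AFDN in the non-additive contrast of Co2, at -0.02 and not called, was at 0.00706 with loess, 0.0182 with chromosome and 0.0651 with window centring, and between -0.294 and 0.184 when 1 library was left out.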

Other observations

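The tests of other splits given here were chosen only after their results were seen, and KHDC1 was picked after its values were seen. KHDC1 stood at 38.0 ± 8.38 CPM in Co1 and 1.92 ± 1.24 in MOCK. Of 26 interferon response genes 3 rose and 1 fell in Co1 against MOCK, with IRF7 at 1.32 ± 0.24 (log2 fold change, SE), MX1 at 1.01 ± 0.29 and USP18 at -0.98 ± 0.27; as a list they did not pass the test (adjusted p = 0.699, camera). Of 26 neuronal genes 4 rose and 2 fell (list adjusted p = 0.402). The neurofilament genes NEFL (1.05 ± 0.19) and NEFM (1.00 ± 0.23) were higher and NRXN3 (-0.94 ± 0.24) lower. With windows centred, USP18 (-0.47, adjusted p = 0.348), NEFL (0.47, adjusted p = 0.115) and NEFM (0.42, adjusted p = 0.316) were not called.

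A gene overlapping RPL13A was chosen after seeing the values. AC010619.2, whose gene ID is also among those of the RPL13A row, had 416 ± 18.0 CPM in MOCK, 141 ± 14.2 with MLL-AF6 and 141 ± 5.99 with exMLL-AF6, 301 ± 29.7 in Co1, 327 ± 32.6 with AF6-shMLL, 474 ± 20.5 with AF6-MLL and 476 ± 33.1 in Co2. RPL13A and RPL41 were likewise lowest with MLL-AF6 (56.8 and 35.2 CPM) and exMLL-AF6 (54.2 and 36.0), against 129 and 64.5 in MOCK. Why these rows move alike was not tested, and counts per gene do not tell chromosomal reads from reads of a construct. Rows named for ribosomal RNA took 0.583% ± 0.0356 of non-mitochondrial counts in MOCK and 0.227% ± 0.0206 with AF6-shMLL, with group means of 0.29% to 0.352% elsewhere (exact two-sided permutation p = 0.1 for each group against MOCK, the smallest possible). Olfactory receptor rows, at genes closed in most cells, took 0.167% ± 0.00209 with MLL-AF6 (exact p = 0.1 against MOCK), 0.137% ± 0.00919 in Co1 (exact p = 0.1), 0.135% ± 0.0222 with AF6-MLL (exact p = 0.3), 0.126% ± 0.00769 with exMLL-AF6 (exact p = 0.2), 0.121% ± 0.00387 in Co2 (exact p = 0.4) and 0.115% ± 0.0211 with AF6-shMLL (exact p = 0.7), against 0.105% ± 0.0182 in MOCK.

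With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split and the highest of the other 9 gave 278 and 5 calls for MLL-AF6 vs MOCK, 51 and 1 for AF6-MLL, 2492 and 1 for Co1, 135 and 0 for exMLL-AF6, 145 and 1 for AF6-shMLL, and 143 and 9 for Co2. They gave 12 and 2 for exMLL-AF6 vs MLL-AF6, 42 and 11 for AF6-shMLL vs AF6-MLL, 1926 and 1 for Co2 vs Co1, 1827 and 0 for Co1 vs MLL-AF6, 1636 and 0 for Co1 vs AF6-MLL, and 17 and 0 for Co2 vs exMLL-AF6. In each of these the real split (1 of 10) was the highest. For Co2 vs AF6-shMLL the real split gave 2 and another 7, so that 2 of 10 splits gave as many.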
